A study of Homo sapiens with 6 samples.

How the data were processed

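RNA from ES2, a human ovarian cancer cell line, was sequenced in 6 libraries. Per the labels, 3 libraries came from cells given a control antisense oligonucleotide (control ASO) and 3 from cells given an antisense oligonucleotide against RUNX1-IT1 (RUNX1-IT1 ASO), a long non-coding RNA transcribed from within the RUNX1 gene. An antisense oligonucleotide is a short nucleic acid strand that pairs with a target RNA, often to have it degraded. Per the labels' protocols, the libraries were mRNA-focused and were made from total RNA. The labels number the replicates 1 to 3 in each group and do not say whether these came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

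Per the submitters' processing notes, the genome build was GRCh38, and FastQC 0.11.9 and fastp 0.22.0, a quality report tool and a read trimmer, were used. The aligner, the counting tool, the gene annotation, the strand setting and any filter on genes were not given in the sources used here. The values deposited by the authors are in CPM, read counts scaled to library size, with 1 value per entry and library. This unit was read from the values themselves. Low values in each library fell on evenly spaced steps, as one read's worth of CPM would give. Each library's table held the same 1113 entries, of which 771 carried a gene symbol and 342 (30.7%) carried none.

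The entries made up 1.02 to 1.11% of the CPM scale in the control ASO libraries and 0.363 to 0.389% in the RUNX1-IT1 ASO libraries, so the tables hold a small part of each library. All entries but 1 differed at least 2-fold between the group means, and the smallest fold was 1.99. The 1113 entries are therefore treated as genes already selected for a difference between these same samples. Statements on the rest of the transcriptome are not made. From the step size, 1 read was worth 0.0471 to 0.0579 CPM in the control ASO libraries and 0.0535 to 0.0586 CPM in the RUNX1-IT1 ASO libraries. These steps put the totals at 20100000, 17300000 and 21200000 reads in control ASO replicates 1, 2 and 3, and 18700000, 18600000 and 17100000 in RUNX1-IT1 ASO replicates 1, 2 and 3. All checked values up to 320 steps lay within 0.1 step of a whole number. A floor of 3 reads corresponds to 0.141 to 0.176 CPM, which covers counting error only. The smallest values above 0 lay at 1 step in each RUNX1-IT1 ASO library but at 2, 5 and 2 steps in control ASO replicates 1, 2 and 3, so whole reads were not taken as recovered for the control ASO libraries. Their totals and floors are less certain for that reason, and no test of differential expression was run on read counts.

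The design had allowed for either counts or normalised values, and the test for normalised values was used. In R 4.3.3, limma 3.58.1 was fitted to log2(CPM + 1) with a mean-variance trend, with group as the only term. The 489 named genes with a mean of at least 1 CPM over the 6 libraries were tested, and 282 were not. Changes are RUNX1-IT1 ASO minus control ASO on the log2(CPM + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no minimum fold. Entries without a symbol, 9.35 to 10.4% of the listed CPM, were kept out of the main tests and described separately. Unless another measure is named, errors of CPM values are SD with n = 3 libraries per group, and errors of log2 changes are limma standard errors.

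Gene lists were fixed before the data were examined, 23 in all, covering pathways, complexes, quality measures and cell type markers. The 8 lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other listed genes only. The rule for named genes was also set before the data were examined. It took up to 10 genes in each direction with the largest changes among genes past the threshold, with a mean at or above the 25th percentile of tested genes and the libraries of the groups not overlapping, and up to 4 members of each list with the smallest adjusted p. It also took a few genes by name, of which RUNX1-IT1, RUNX1, RUNX2 and STAT2 are not listed in the tables used here and 1 is not reported here. The knockdown target could therefore not be used to check the labels. Genes named outside this rule are said to be chosen after their values were seen.

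Symbols were matched to an NCBI gene table and to GENCODE release 29 on GRCh38. Of the 771 symbols, 679 were current, 54 were synonyms, 32 were gene numbers and 6 were unmatched, and 734 had coordinates. Replicates were compared by a chi-square of their implied reads. Chi-square per degree of freedom was 2.34 to 3.45 for pairs of RUNX1-IT1 ASO libraries, so none agreed within sampling noise. It was 2.17 to 2.80 for pairs of control ASO libraries, where it rests on the less certain totals. The limma step was tested on simulated values from 499 to 516 genes per run in 5 runs of this comparison. It called 95.7% of genes simulated at 0.5-fold, 97.6% at 2-fold, 100% at 0.25-fold and 100% at 4-fold, and 0.823% of unchanged genes. Each run changed 200 genes, as many up as down, whereas nearly all listed genes fell, so these rates may not carry over to the listed genes. Alternatives covered scaling, the low-value filter, the pseudocount, the limma trend, the thresholds, a replicate block and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.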

Results

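The series measured gene expression in ES2 ovarian cancer cells under a control ASO (3 libraries) and under an ASO against RUNX1-IT1 (3 libraries), and the question in its design is how knockdown of this non-coding RNA changes expression. The listed entries summed to 10803, 10176 and 11070 CPM in control ASO replicates 1, 2 and 3. They summed to 3628, 3812 and 3894 CPM in RUNX1-IT1 ASO replicates 1, 2 and 3. Implied totals were 17100000 to 21200000 reads per library. Over the 188 entries with a mean of at least 5 CPM, the median coefficient of variation between replicates was 6.49% in the control ASO group and 11.1% in the RUNX1-IT1 ASO group. Nearly all listed entries were lower in the RUNX1-IT1 ASO group, where counting error weighs more. These values therefore do not by themselves show that its replicates were noisier. RUNX1-IT1 and its host gene RUNX1 are not listed in the tables used here, so the level of the target is not analysed here.

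RRAD, ATF3, ARC and SNAI1 had the largest decreases on the log2(CPM + 1) scale under the RUNX1-IT1 ASO by the rule for named genes, an order that does not hold by fold. RRAD, a Ras-related GTPase gene, stood at 18.7 ± 1.94 CPM in control ASO libraries and 1.22 ± 0.162 CPM in RUNX1-IT1 ASO libraries (SD, n = 3 each), 15.4-fold lower. ATF3, a stress-induced transcription factor, went from 58.8 ± 1.49 to 6.16 ± 0.829 CPM, 9.54-fold lower. ARC, an immediate early gene best known from neurons, was 9.41-fold lower, and SNAI1, a repressor of the E-cadherin gene, was 8.68-fold lower. LINC00894, a non-coding RNA, rose 2.24-fold, from 1.42 ± 0.284 to 3.17 ± 0.514 CPM, and FBLN7, a fibulin of the extracellular matrix, rose 2.19-fold, from 1.15 ± 0.182 to 2.51 ± 0.516 CPM.

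On the log2 scale RRAD fell by 3.15 ± 0.12 (SE, limma, adjusted p = 1.2e-10) and ATF3 fell by 3.07 ± 0.10 (limma, adjusted p = 1.2e-10). The listed genes appear to be selected for a difference between these same samples. Adjusted p-values of single genes, taken over such genes only, are therefore not independent evidence of a change. All 3 RUNX1-IT1 ASO libraries lay below all 3 control ASO libraries for the 10 genes that fell, and above them for LINC00894 and FBLN7. The rule for named genes required this separation, so it adds no evidence. ARL14, an Arf-like GTPase gene, fell from 11.9 ± 0.978 to 0.874 ± 0.364 CPM. ID2, an inhibitor of helix-loop-helix transcription factors, fell from 16.9 ± 1.43 to 1.59 ± 0.333 CPM, and RND1 from 14.6 ± 1.10 to 1.29 ± 0.171 CPM. ALOXE3, an epidermal lipoxygenase gene, fell 10.8-fold and TRAF1, an adaptor of tumour necrosis factor receptor signalling, fell 7.48-fold. PAX8-AS1, a non-coding RNA gene opposite PAX8, fell 7.40-fold, and its reads cannot be told apart from those of PAX8 where the counting did not use strand, a limit shared by LINC00894, which is annotated as antisense. LINC00894 (limma, adjusted p = 0.000123) and FBLN7 (limma, adjusted p = 0.000366) changed by 0.79 ± 0.14 and 0.70 ± 0.14 on the log2 scale. Rescaling to equal totals over the listed entries moved RRAD to -2.04, ATF3 to -1.68, LINC00894 to 1.84 and FBLN7 to 1.69, all still called. Rescaling raises the RUNX1-IT1 ASO libraries relative to the controls, so for LINC00894 and FBLN7, which rose, the kept call is no test. In GENCODE release 29 on GRCh38, RRAD lies on chromosome 16 from 66921679 to 66925644, ATF3 on chromosome 1 from 212565334 to 212620777, and LINC00894 on chromosome X from 149938628 to 150224580.

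**Figure D1:**
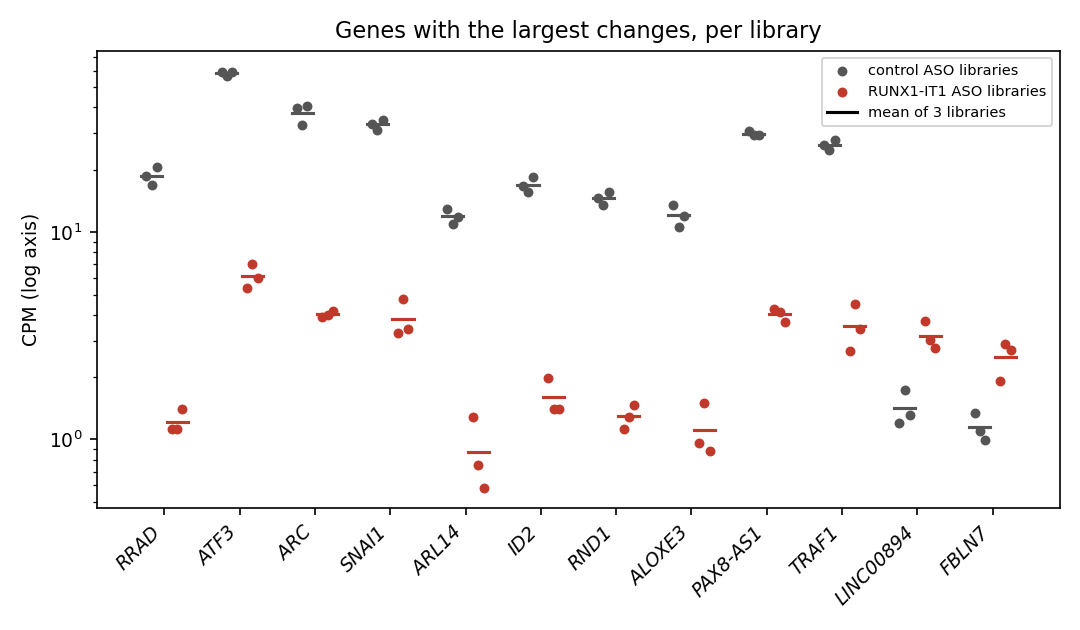
CPM per library (log axis) of the 12 genes named by size of change, with control ASO libraries in grey, RUNX1-IT1 ASO libraries in red and bars at the mean of 3 libraries. RRAD sits near 18.7 CPM under the control ASO and near 1.22 CPM under the RUNX1-IT1 ASO, while LINC00894 and FBLN7 are the genes plotted that lie higher under the RUNX1-IT1 ASO.

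Of the 489 genes tested, 477 were lower and 10 were higher under the RUNX1-IT1 ASO at an adjusted p under 0.05 in limma. The 2 tested genes that did not pass, named after their values were seen, were F8A2 (adjusted p = 0.0521) and HIST2H4B (adjusted p = 0.109), both of which have near-identical copies in the genome. All RUNX1-IT1 ASO libraries lay below all control ASO libraries for 475 genes and above them for 10, where chance separates 10% of genes with 3 libraries against 3. The median change was -1.12, and the 25th and 75th percentiles were -1.43 and -0.88. Among all listed entries, 1081 had the lower mean under the RUNX1-IT1 ASO and 32 the higher. Nearly all listed genes differed at least 2-fold between these same samples, so these counts are not independent evidence of a change. Rescaling the libraries to equal totals over the listed entries moved the median to -0.06 and the calls to 118 lower and 43 higher. By construction this centres a set of genes that nearly all fell. For a gene that fell, a positive value after rescaling marks a smaller fall than that of the listed total.

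**Figure D2:**
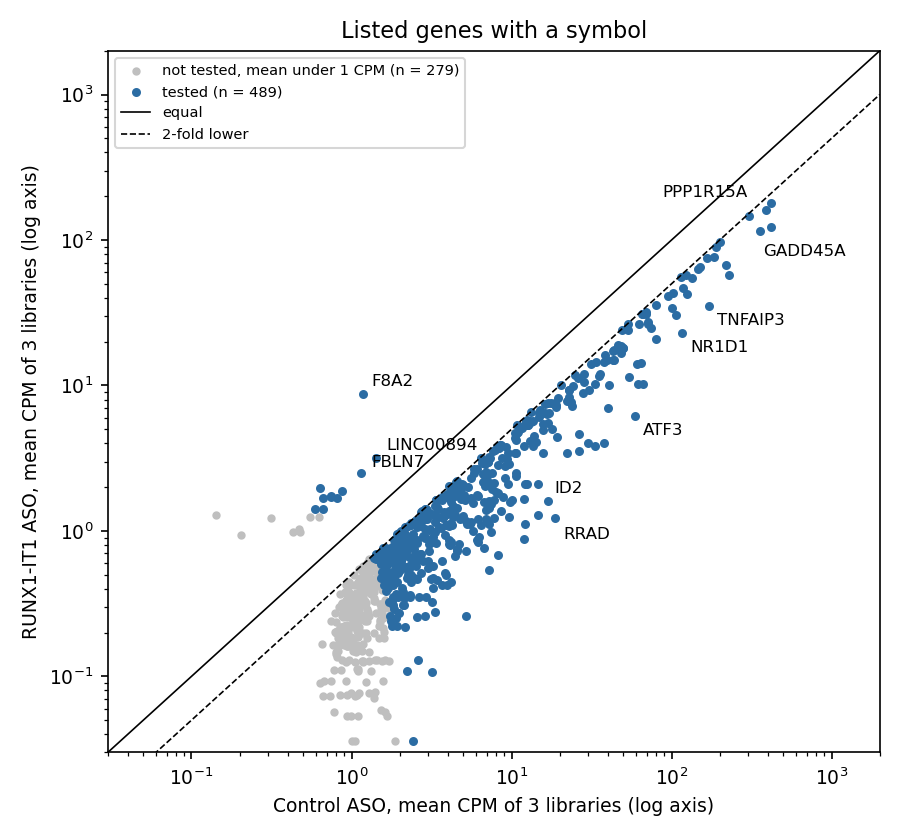
Mean CPM of 3 libraries under the RUNX1-IT1 ASO against the control ASO (both log axes) for 768 listed genes with a symbol, 3 genes at 0 in a group being left out, with lines of equal level and of a 2-fold lower level. The 489 tested genes are blue and nearly all lie under the dashed line, apart from the higher group that includes LINC00894, FBLN7 and F8A2, and rescaling to equal totals would move the median change to -0.06.

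The question for the gene lists was whether members of a pathway moved together under the RUNX1-IT1 ASO. Since 477 of the 489 tested genes were called lower, with a median of -1.12 over all 489, members that all fell do not show this by themselves. Of 93 genes on the NF-kB list, 25 were listed and 24 tested, and all 24 fell, with a median of -1.34, though after rescaling to equal totals 10 were called lower, 2 higher and 12 neither, with a median of -0.16. TNFAIP3, a deubiquitinating enzyme that restrains NF-kB, dropped 4.87-fold from 171 ± 7.05 to 35.1 ± 2.88 CPM. BIRC3, an inhibitor of apoptosis gene, dropped 3.86-fold. Of 56 immediate early and MAPK feedback genes, 20 were listed and tested, and all 20 fell, with a median of -1.72, and after rescaling 12 were called lower, 1 higher and 7 neither, with a median of -0.41. FOSB, a subunit of the AP-1 transcription factor, fell from 65.9 ± 3.38 to 10.3 ± 0.569 CPM, and KLF10, a TGF-beta-inducible zinc finger factor, from 220 ± 7.58 to 67.5 ± 1.28 CPM.

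Among p53 targets and apoptosis genes, 13 of 67 were listed and all 13 fell, with a median of -1.27, though after rescaling 6 were called lower, 3 higher and 4 neither, with a median of -0.16. GADD45A, a stress-induced growth arrest gene, fell from 420 ± 27.2 to 123 ± 12.02 CPM, and CDKN2B, a cyclin-dependent kinase inhibitor, fell 4.28-fold. The list of TGF-beta and YAP targets had 6 of 50 members listed, and all 6 fell, with a median of -1.62, led by ID2. THBS1, the matrix protein thrombospondin, was 2.31-fold lower and changed sign to 0.29 after rescaling. After rescaling 3 of these 6 were called lower, 1 higher and 2 neither, with a median of -0.15. These lists share members, and 10 of the 100 listed genes on the fixed lists stand on more than 1 list. Against the other listed genes, camera gave adjusted p = 0.0119 for NF-kB, 0.000707 for immediate early genes, 0.0477 for p53 targets and 0.0477 for TGF-beta and YAP targets. With an estimated correlation none of these calls held, at adjusted p = 0.323 with an estimated correlation for the NF-kB, immediate early and TGF-beta lists and adjusted p = 0.436 with an estimated correlation for the p53 list. Adjusted over the list alone, 24, 20, 13 and 6 members fell on these 4 lists, and since the listed genes appear to be selected on these samples this is not independent evidence. Without control ASO replicate 3 or RUNX1-IT1 ASO replicate 3, the p53 list stood at adjusted p = 0.0603 and 0.0991 and the TGF-beta and YAP list at the same values, and without RUNX1-IT1 ASO replicate 1 the p53 list stood at 0.0519 (camera). After rescaling to equal totals the camera calls of the NF-kB (adjusted p = 0.576), p53 (0.755) and TGF-beta and YAP (0.576) lists were lost, and with a mean of at least 5 CPM those of the NF-kB (0.0851) and p53 (0.0851) lists. With a replicate block the p53 and the TGF-beta and YAP lists also lost their calls, both at adjusted p = 0.0602 (camera). Camera weighs each change against its error, so where nearly all genes fell, a list of well-measured genes can rank low at an ordinary change. The calls were not separated from expression level. With a pseudocount of 0.1 the TGF-beta and YAP median was -1.65, against -1.50 over all tested genes, though camera still called the list (adjusted p = 0.0341).

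In the unfolded protein and amino acid stress list, 8 of 79 members were listed and all 7 tested members fell, with a median of -1.39 (camera, adjusted p = 0.0641; adjusted p = 0.436 with an estimated correlation). DDIT3, a transcription factor of the endoplasmic reticulum stress response, fell 4.47-fold. PPP1R15A, a phosphatase subunit that reverses translational arrest, fell from 416 ± 14.1 to 179 ± 14.03 CPM, and SLC3A2, the shared heavy chain of several amino acid transporters, from 391 ± 23.5 to 161 ± 17.8 CPM, although both turned positive after rescaling to equal totals, at 0.28 and 0.22. All 7 fell adjusted over the list alone. This list passed the camera threshold without control ASO replicate 1 (adjusted p = 0.04), control ASO replicate 2 (0.0322) or RUNX1-IT1 ASO replicate 2 (0.0405), with no filter on low values (0.0117) and with a pseudocount of 0.1 (0.0459). After rescaling 2 of the 7 were called lower, 2 higher and 3 neither, with a median of -0.1.

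Epithelial-mesenchymal transition, matrix and adhesion genes had 7 of 131 listed, and all 5 tested fell, with a median of -1.40 (camera, adjusted p = 0.145; adjusted p = 0.323 with an estimated correlation). After rescaling to equal totals 2 of the 5 were called lower, 1 higher (THBS1, 0.29) and 2 neither, with a median of -0.12. MMP10 and MMP19, matrix metalloproteinase genes, were 7.13-fold and 3.11-fold lower, and MMP19 was no longer called after rescaling (-0.12). Replication-dependent histone genes had 13 of 55 listed, and all 9 tested fell, with a median of -1.21, though after rescaling 1 was called lower and 8 neither, with a median of -0.14. HIST2H2BE fell 4.51-fold, HIST2H2AA3 fell 3.13-fold, HIST1H2AG fell 3.10-fold and HIST1H2BD fell 3.66-fold, and after rescaling HIST2H2AA3 (-0.14), HIST1H2AG (-0.11) and HIST1H2BD (-0.28) were no longer called. Reads of some histone genes, among them HIST2H2AA3, can be shared with near-identical copies. Camera did not separate the histones from the other listed genes (adjusted p = 0.964, and adjusted p = 0.974 with an estimated correlation). Its direction was up, which is relative to those genes and does not mean that the histones rose. Adjusted over the list alone, all 5 and all 9 fell.

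The oxidative stress and NRF2 list had 5 of 92 members listed. TXNIP, a thioredoxin-binding protein gene, fell from 150 ± 3.17 to 65.0 ± 2.05 CPM, HMOX1, the heme-degrading enzyme, from 65.0 ± 4.22 to 31.0 ± 2.15 CPM, ABCC2, an efflux transporter, 2.18-fold and OSGIN1 2.22-fold, though TXNIP, HMOX1, ABCC2 and OSGIN1 stood at 0.29, 0.42, 0.34 and 0.31 after rescaling to equal totals. NOX5, a superoxide-producing oxidase gene named after its values were seen, rose from 0.639 ± 0.1004 to 1.97 ± 0.264 CPM. The list's median was -1.04 and turned to 0.34 after rescaling. Camera, which compares with the other listed genes only, placed it above them at adjusted p = 0.101 (adjusted p = 0.323 with an estimated correlation), and after rescaling called it as higher (camera, adjusted p = 0.0023). Rescaling centres the listed genes by construction, so this call is relative to them and does not show that the list rose. Adjusted over the list alone, 4 fell.

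Lists with fewer than 5 tested members were not tested as sets. Of interferon response genes, 5 of 92 were listed and all 4 tested fell. IFIT2, an interferon-induced antiviral gene, fell from 22.3 ± 2.42 to 3.44 ± 0.293 CPM, IRF1, an interferon regulatory factor, fell 2.89-fold, MX1, an antiviral GTPase, fell 3.41-fold and IFIT3 fell 2.03-fold. After rescaling to equal totals IRF1 (-0.03) and MX1 (-0.13) were no longer called and IFIT3 turned to 0.42. Of 77 hypoxia genes 3 were listed, and all 3 fell. ADM, the peptide hormone adrenomedullin, fell 4.35-fold, CITED2, a CBP-binding regulator of hypoxia signalling, fell 2.23-fold and ANGPTL4, an inhibitor of lipoprotein lipase, fell 2.46-fold, and CITED2 and ANGPTL4 turned to 0.34 and 0.19 after rescaling. Of 65 cholesterol and lipid genes 4 were listed and 3 tested, and ABCA1, a cholesterol exporter, fell 2.73-fold, PPARGC1A, a coactivator of mitochondrial biogenesis, fell 3.03-fold and MYLIP, which degrades the low-density lipoprotein receptor, fell 2.15-fold, with ABCA1, PPARGC1A and MYLIP at 0.05, -0.10 and 0.35 after rescaling, none of them called.

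PDK4, a pyruvate dehydrogenase kinase, was the 1 member of 36 glycolysis genes listed and fell 3.26-fold, and was no longer called after rescaling to equal totals (-0.13). Among 30 ovarian tumour and epithelial markers, PAX8, a transcription factor of the Müllerian epithelium, fell from 7.16 ± 0.733 to 2.98 ± 0.602 CPM, and ESR1, the estrogen receptor alpha gene, fell from 2.42 ± 0.279 to 0.828 ± 0.0254 CPM, though neither was called after rescaling, at 0.19 and -0.03. Of 26 immune cell markers 1 was listed, ITGAM, at 1.72 ± 0.113 and 0.127 ± 0.0792 CPM, and its mean was too low for the test. Adjusted over the list alone, all tested members of the interferon (4), hypoxia (3), cholesterol and lipid (3), glycolysis (1) and ovarian (2) lists fell. No member was listed for cell cycle and DNA replication (153 genes), nuclear-encoded oxidative phosphorylation (81), ribosomal proteins (80), housekeeping genes (36), the RUNX1 locus and RUNX family (21), fibroblast and mesothelial markers (16), mitochondrially encoded genes (15), the NuRD complex (15) or endothelial markers (14). In fry, which asks whether a list moves one way and makes no comparison with other genes, p ranged from 1.91e-06 to 4.87e-05 over the 8 lists in limma. The listed genes appear to be selected for a difference between these same samples, so low fry p-values would arise for nearly any list and are not independent evidence.

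**Figure D3:**
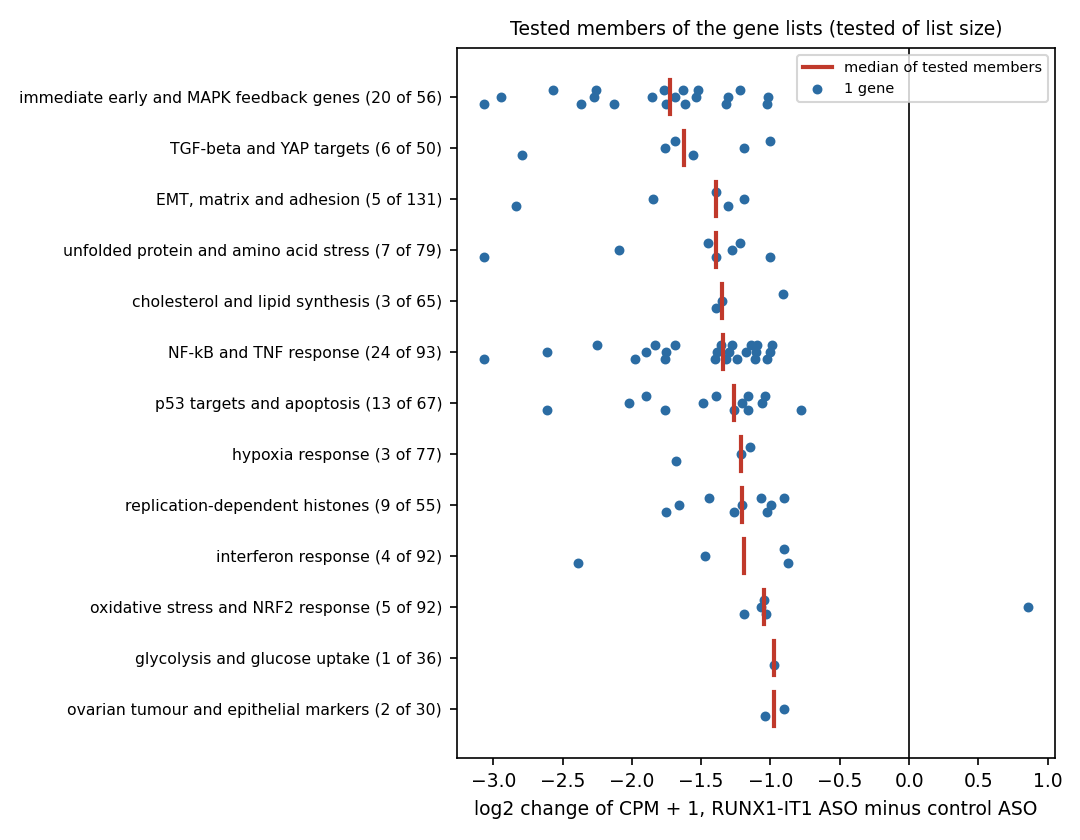
Change of each tested list member on the log2(CPM + 1) scale, RUNX1-IT1 ASO minus control ASO, for the fixed gene lists, with red bars at the list median and the tested and total number of members in brackets. All plotted members lie below 0 except NOX5, with medians from -1.72 for immediate early genes to -0.97 for ovarian markers, and after rescaling to equal totals the medians of the oxidative stress (0.34), hypoxia (0.19), ovarian (0.08) and cholesterol (0.05) lists turn positive.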

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

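Of the tests in this part, the count over splits of the libraries was planned, and the tests of a scaling factor, of DNA or unspliced RNA and of the choice of genes were chosen only after the result was seen.

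Among the 342 entries with no gene symbol, which were kept out of the main tests, 7 were higher in every RUNX1-IT1 ASO library than in every control ASO library. The highest-ranked was at 0 in all control ASO libraries and at 2.42 to 4.86 CPM in the RUNX1-IT1 ASO libraries. In the opposite direction, 324 of these entries were lower in every RUNX1-IT1 ASO library. The entries appear to be selected for a difference between these same samples, so neither count is evidence beyond that selection.

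The pattern most in need of a second look is its one-sidedness, with 1081 entries lower and 32 higher. A single scaling factor between the groups would lower all genes alike, but over 140 tested genes at 10 CPM or more in the controls the SD of log2 changes was 0.526 against a median standard error of 0.104, which argues against it as the whole cause. Genomic DNA or unspliced RNA spread evenly over the genome in the control libraries would lose a similar CPM per kb of exon everywhere, but the 75th percentile was 5.25 times the 25th over 137 genes at 10 CPM or more and 3.86 times over 577 genes under 10 CPM. These values bear on an even spread only, and unspliced RNA whose level differs between genes was not tested. That test was first run on all 714 genes together, at 7.24 times, and then divided by level. How the genes were chosen stays open and cannot be told apart from a real excess of lower genes, since the smallest fold listed is 1.99. An effect of the ASO, a partial scaling difference and a difference in handling between the groups stay open too. Over 10 splits of the libraries, the real split gave 487 genes and the highest other gave 1 gene. So few splits cannot give a share under 0.05. The entries also appear to be selected for a difference between the real groups, so few calls in the other splits follow from that selection and the count decides nothing.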

How the results depend on the processing

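The alternatives here were planned except the one that tested entries without a symbol, which was chosen after the data were seen. The 487 genes called became 161 after rescaling to equal totals over the listed entries, 165 with a mean of at least 5 CPM, 309 with at least a 2-fold change on the log2(CPM + 1) scale, which understates the fold of low genes, and 769 with no filter on low values. The filter counts follow from the number of genes tested (165 and 771), the fold count from its added condition, and rescaling by construction centres a set of genes that nearly all fell. With entries without a symbol tested too, 669 of 670 passed. Leaving out each library in turn gave 487 to 489 genes, and all 487 were among them each time. Since the entries appear to be selected for a difference between these same samples, that is not independent evidence. The 10 higher calls fell to 0 under the mean of at least 5 CPM and under the 2-fold condition. Camera called 4 lists and after rescaling 2, the immediate early list (adjusted p = 0.0034) and the oxidative stress list, which was not among the 4 and stood higher than the other listed genes (0.0023). It called 2 with a mean of at least 5 CPM, losing NF-kB and p53, 5 with no filter, 5 with a pseudocount of 0.1, 0 with an estimated correlation (0 also at an unadjusted p under 0.05, against 8 in fry) and 2 to 5 when a library was left out; the lowest, 2, came without control ASO replicate 3 and without RUNX1-IT1 ASO replicate 3. Apart from the share due to fewer genes, the cause was not tested.

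With the replicate number as a replicate block, 488 genes and 2 lists passed, the p53 and the TGF-beta and YAP lists moving to adjusted p = 0.0602 (camera). Same-numbered libraries correlated at -0.24, -0.10 and -0.02, and none correlated best with its own number, so the numbers were not taken to pair the samples.

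Of the 45 genes named by the rule, 7, among them LINC00894 and FBLN7, missed the 2-fold condition, and 10 were not tested with a mean of at least 5 CPM. Under rescaling 13 changed sign, 8 of them past the threshold and 5 not, 9 kept their sign but lost their call and 23 kept both. Among those that kept both were LINC00894 and FBLN7, which rescaling moves further up. Where tested, none changed direction or call under the alternatives for the trend, filter, pseudocount, block, entries without a symbol and left-out libraries. The rule took these genes for large changes or small adjusted p-values in these same libraries, so this stability follows largely from the choice. The oxidative stress list median turned to 0.34. The genes that changed sign were IFIT3 (0.42), TXNIP (0.29), HMOX1 (0.42), ABCC2 (0.34), OSGIN1 (0.31), CITED2 (0.34), ANGPTL4 (0.19), THBS1 (0.29), PPP1R15A (0.28), SLC3A2 (0.22), ABCA1 (0.05), MYLIP (0.35) and PAX8 (0.19). Scaling by housekeeping genes was not run because none is listed in the tables used here, and the alternatives that need read counts (a second size-factor scaling, a Wald test, voom) were not run on CPM. No alternative could be run for RUNX1-IT1 itself. Depth limits genes near the floor of 0.141 to 0.176 CPM.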

Other observations

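Of the tests in this part, those of poly(A) selection and of shared copies were chosen only after the result was seen, and the gene groups other than the replication-dependent histones were put together after the values were seen. Since 477 of the 489 tested genes were called lower, a group whose members all fell is not by itself evidence of a shared change.

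Several genes of the circadian clock were lower. Of 20 clock genes 6 were listed and all 6 fell (limma, adjusted p under the threshold), with a median of -1.35. NR1D1, the nuclear receptor REV-ERB alpha, fell from 117 ± 3.78 to 22.9 ± 2.01 CPM (SD, n = 3 each), 5.11-fold lower. TEF, a clock-output transcription factor, fell 3.48-fold, and NOCT, the circadian gene nocturnin, fell 2.95-fold from 43.9 ± 3.30 to 14.9 ± 1.12 CPM. PER2, a core repressor of the clock, fell 2.40-fold and CIART, a clock-associated repressor, fell 2.41-fold, and DBP went from 1.96 ± 0.803 to 0.510 ± 0.211 CPM. After rescaling to equal totals 1 of the 6, NR1D1 (-0.84), was still called, while TEF (-0.27), NOCT (-0.06), DBP (-0.23), PER2 (0.22) and CIART (0.21) were not.

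Of 17 interleukin, tumour necrosis factor family, chemokine and colony-stimulating factor genes listed, all 14 tested fell, with a median of -1.19, but after rescaling 5 were called lower, 1 higher and 8 neither. IL6, a cytokine of inflammation, fell 5.89-fold from 6.47 ± 0.589 to 1.10 ± 0.253 CPM, IL32 fell 4.49-fold and CSF1, the macrophage growth factor, fell 3.08-fold, with CSF1 at -0.11 and no longer called after rescaling. IL11, a cytokine of the same receptor family as IL6, fell 2.06-fold from 49.3 ± 1.18 to 23.9 ± 1.63 CPM but stood at 0.44 after rescaling. All 16 listed ZNF zinc finger genes fell, with a median of -0.86 that turned to 0.22 after rescaling, when 1 (ZNF280A, -0.57) was called lower, 2 higher and 13 neither.

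Several RNAs made without a poly(A) tail were lower, in libraries that the labels call mRNA-focused, as were the 9 tested replication-dependent histone genes, whose messages mostly lack one. Of 25 such RNAs 7 were listed and all 5 tested fell, among them SNORD3A, a small nucleolar RNA, from 19.2 ± 1.08 to 4.40 ± 0.533 CPM, RN7SK, which holds back transcription elongation, 3.87-fold, and RNU12, a minor spliceosome RNA, 2.65-fold, and after rescaling SNORD3A (-0.58) and SNORD3D (-0.31) were still called, while RN7SK (-0.34), RPPH1 (-0.33) and RNU12 (0.07) were not. Weaker poly(A) selection in the control libraries might lower all of them by 1 common factor, and Cochran's Q against a common factor was 12.5 on 4 degrees of freedom, between the 95th (9.49) and 99th (13.3) percentiles of chi-square set as its bounds after the earlier forms were seen, so the test leaves this open. It was the last of several forms tried: the range of changes was first set against 3 median standard errors, at 0.97 against 0.121 with a pseudocount of 1 and then at 0.77 against 0.178 with a pseudocount of 0.1, and both of these forms argued against a common factor. The reading therefore depends on the form of the test, and no biological explanation was tested. The listed RNAs also appear to be selected for a difference between these same samples. Those with a smaller difference would not be listed, which narrows the spread, so none of these forms could show a common factor.

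Copies of a gene can divide reads between them. HIST2H4A and HIST2H4B, near-identical histone genes, read 21.8 and 0 CPM in control ASO replicate 1 but 2.43 and 16.6 CPM in control ASO replicate 2. If shared reads were divided arbitrarily the sum should vary less, and its coefficient of variation over the control libraries was 6.93%, against 77.5% and 108% for the copies alone, in line with shared reads as a candidate explanation. The sum went from 20.3 ± 1.41 to 3.34 ± 0.435 CPM, 6.08-fold lower. F8A2, another gene with near-identical copies, read 0, 16.6 and 9.61 CPM in the RUNX1-IT1 ASO libraries.

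Of 11 entries named for microRNAs, 10 had the lower mean under the RUNX1-IT1 ASO and 1, MIR296, the higher, at 0.549 ± 0.173 and 1.25 ± 0.207 CPM. The MIR6883 entry went from 101 ± 6.27 to 33.9 ± 3.34 CPM, and it lies within PER1, on chromosome 17 from 8144994 to 8145071 (GRCh38), a clock gene not listed in the tables used here. MIR22, within its host transcript, went from 31.5 ± 2.42 to 13.99 ± 0.756 CPM, and MIR6732, within ZC3H12A, from 12.4 ± 0.756 to 5.81 ± 0.615 CPM. After rescaling MIR22 and MIR6732 turned to 0.32 and 0.36, both called higher, and MIR6883 (-0.07) was not called. Reads of the microRNA and of its host cannot be separated from these values.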
